A study of Caenorhabditis elegans with 71 samples.

How the data were processed

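Poly(A) RNA of whole Caenorhabditis elegans larvae was sequenced along 4 time courses. Per the labels' protocols, larvae hatched without food, which holds them in the first larval stage, and time runs from their transfer to plates with bacteria. The 71 libraries came from 4 populations. Wild type N2 at 20C was sampled in one population from 0 to 38 h every 2 h (20 libraries, called DH2) and in an independent one from 38 to 48 h (6 libraries, DH5). Wild type at 25C was sampled from 0 to 28.5 h every 1.5 h (20 libraries, DH3), and the lin-4(e912) mutant at 20C from 0 to 48 h every 2 h (25 libraries, DH4). Each time point is 1 library. The test statistics below therefore measure the spread between time points of a population, and genotype or temperature cannot be told apart from the population that carried it.

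The deposited values are RPKM (reads scaled by gene length and by library size), the unit that the authors gave in naming the table. Reads were aligned with BWA 0.5.9 per the submitters' processing notes. The genome build, the annotation, the counting rule and the use of strand are not given in the sources used here. Coordinates are therefore not given, and values of near-identical or overlapping genes could hold shared reads. The table holds 21777 entries. Of these, 2643 carry RIT identifiers with no gene name and 11 others carry no name. They took 1.58 to 3.03% of summed RPKM per library and were left out, which leaves 19083 genes. Of these, 18694 matched a current symbol in the reference gene tables. 3 identifiers listed with 2 names had identical values and were kept once, and 58 names are carried by more than 1 identifier. Cells without a value were taken as 0, since the table holds no 0 and such cells occur in genes with few reads: among 2333 low genes of DH5, 7106 cells were empty where a Poisson model gives 6243 without a read.

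Depth was estimated from the steps between low values. Of 7080 genes below 1 RPKM, 98.1% were whole multiples of one read's worth in every library, within a tolerance of 0.001. Steps of 4891 genes with 1 annotated transcript in the WBcel235 annotation, 107 of which agree on the most common value, put the depth at 12.3 to 36.5 M reads per library. These absolute depths are estimates, because the authors' annotation is unknown, and relative depths do not need it. The median was 19.8 M for DH2, 23.7 M for DH3, 29.0 M for DH4 and 30.3 M for DH5.

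All tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), for genes with a mean RPKM of at least 1 over the libraries compared. Every fold is on that scale, which understates changes of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1 log2 unit, except for amplitude differences (below). Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 read the table and drew the plots. Designs, gene lists, the rule for named genes and most alternatives were fixed before the data were examined, and the others are stated as later choices.

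Oscillation was tested in 17 libraries of each series, from 6 to 38 h at 20C and from 4.5 to 28.5 h at 25C. The first time points were left out because larvae leave arrest there. A cosine and a sine term were tested together beside a natural spline of time with 3 degrees of freedom. The period of a series was the one, from 4 to 12 h in steps of 0.25 h, with the highest mean partial R2 over tested genes. The effect is the fitted peak-to-trough range. Trends were tested as the linear coefficient of time beside cosine and sine terms, and are given as the fitted change over the window. The lin-4 mutant was compared with wild type over 17 pairs of equal labelled time from 6 to 38 h against DH2, with time as a factor, as a mean difference and as a change of that difference with time. It was also compared over 6 pairs from 38 to 48 h against DH5. Amplitude differences between lin-4 and wild type used the delta method, a normal approximation and Benjamini-Hochberg adjustment over genes oscillating in either series, and a gene was called there at an adjusted p under 0.05 with no minimum size. For 25C against 20C, 25C time was multiplied by the factor, from 1.1 to 1.9 in steps of 0.05, with the highest mean correlation of 25C libraries with interpolated 20C libraries. The temperature term was then tested with 16 libraries at 25C, beside a spline of aligned time with 4 degrees of freedom and cosine and sine terms. Fed larvae (6 h at 20C, 4.5 h at 25C) were compared with arrested larvae (0 h) over 3 populations, DH2, DH3 and DH4, with population as a block.

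The pairs follow from the labelled time or population. Deviations from group means correlated within pairs with a median r of 0.441 for lin-4 against DH2 (14 of 17 pairs over 0.1, lowest -0.289), of -0.256 for lin-4 against DH5 (1 of 6 pairs over 0.1, lowest -0.743) and of 0.343 for fed against arrested larvae (all 3 pairs over 0.1, lowest 0.331). These correlations are across genes, which are not independent replicates.

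The gene lists hold heterochronic genes, lin-4 targets (lin-14 and lin-28), cuticle collagens (with dpy-18, an enzyme that modifies collagens, among them), molting factors, hedgehog-related, patched-related and astacin protease genes, pharyngeal cuticle genes (abu and pqn), germline, sperm and yolk protein genes, vulva and gonad development, cell cycle and replication, ribosomal proteins, starvation and first-stage arrest, heat shock and folding, body wall muscle, pharynx muscle and gland, intestine, neurons, epidermis and seam transcription factors, male development, epidermal antimicrobial peptides and reference genes. Calls in a list were counted after adjustment over all tested genes and over the list alone. Lists with at least 3 tested members were compared with other genes by camera, with a preset correlation of 0.01 and with an estimated one, and oscillation calls by Fisher's exact test (two-sided), both with Benjamini-Hochberg adjustment. The rule for named genes takes lin-14, lin-28, lin-41, hbl-1, lin-29, lin-42, daf-12, mlt-10 and nhr-23 in every comparison, the 5 called genes with the largest positive and the 5 with the largest negative change (for oscillation the 10 with the largest range) among genes with a mean RPKM of at least 5 and a symbol other than a sequence name, and up to 4 called members per list. Where a list had no call, it takes the member with the highest mean RPKM. Of the members of lists, the text names a part. lin-4 and F59G1.4, which carries it, were on that list and were not analysed here.

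Each step was tested on simulated data for the tested genes with 200 genes changed by 1.5, 2 or 3 log2 units. For oscillation, the shares recovered at these sizes were 94.0%, 94.0% and 98.5% in wild type at 20C (12767 genes), 85.1%, 89.6% and 97.0% at 25C (12980 genes), and 85.1%, 94.0% and 95.5% in lin-4 (12857 genes). The periods found were 11, 7.75 and 12 h where 11.25, 7.75 and 12 h had been put in. For trends the shares were 89.6%, 95.5% and 98.5% in wild type at 20C, 80.6%, 88.1% and 93.9% at 25C, and 89.6%, 86.6% and 95.5% in lin-4, over the same numbers of genes. For lin-4 against wild type they were 98.5% at each size (12855 genes), and for its change with time 79.1%, 83.6% and 84.8%. At 38 to 48 h they were 80.6%, 92.5% and 87.9% (13077 genes). For 25C against 20C the shares were 98.5%, 100% and 100% (12868 genes), for fed against arrested larvae 59.7%, 77.6% and 90.9% (13370 genes), and for amplitude differences 40.3%, 70.1% and 90.9% (1865 genes). Among unchanged genes at most 0.0469% were called in the tests over all genes and 0.781% in the amplitude test. The simulated residuals were independent between libraries, with no delay and no difference between populations. These shares are therefore no rate of false calls in the real data.

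Alternatives tried were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median-of-ratios rescaling of libraries, all time points, periods 1 h shorter or longer, a linear trend in place of the spline, both 20C wild-type populations in one oscillation fit, fits without the block, a time factor equal to the ratio of the sampling intervals, other first fed time points, a lag of up to 4 h, and leaving out each time point or population. After the data had been seen, these were added: a linear clock that aligns lin-4 with wild-type time, periods up to 16 h, a lin-4 series without its 30 h library, and a 4 h lag at 38 to 48 h. The clock sets wild-type time to 0.9 of lin-4 time minus 1.5 h and uses 19 lin-4 libraries.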

Results

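The series follows gene expression through larval development of the nematode Caenorhabditis elegans and asks how transcripts that cycle with the molts, and those with a trend over time, behave at another temperature and without the microRNA lin-4, a regulator of the timing of larval cell fates. Whole larvae were released from starvation arrest onto food, and poly(A) RNA was sequenced at 20 time points in wild type at 20C (0 to 38 h), at 6 in a further 20C wild-type population (38 to 48 h), at 20 in wild type at 25C (0 to 28.5 h) and at 25 in lin-4(e912) at 20C (0 to 48 h). Each of the 71 libraries is 1 time point of 1 population. Estimated depth ran from 12.3 to 36.5 M reads. Values are RPKM as deposited, and changes are on the log2(RPKM + 1) scale, with standard errors over time points. At 38 h the 2 wild-type populations at 20C were both sampled. Their log2 values correlated across 12275 genes with r = 0.987, genes not being independent replicates, and 189 genes (1.54%) differed by 2-fold or more. Neighbouring libraries within a population, 2 h apart, differed that much in 483 genes (3.93%) at 36 and 38 h of the first and in 25 genes (0.204%, r = 0.995) at 38 and 40 h of the second.

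The expression of lin-4 itself was not analysed here, so the genotype label was read only through its targets. The target lin-14 (T25C12.1), which specifies first-stage fates, fell in wild type at 20C from 189 RPKM at 0 h to 64.2 RPKM at 12 h and 30.2 RPKM at 38 h. In the lin-4 mutant it was at 204 RPKM at 0 h, 127 RPKM at 12 h and 57.9 RPKM at 38 h. The target lin-28 (F02E9.2), an RNA-binding protein that delays later fates, went from 143 RPKM to 7.60 RPKM at 38 h in wild type and from 139 to 29.8 RPKM in the mutant. At 48 h the mutant held 37.1 RPKM of lin-14 and 21.3 RPKM of lin-28, against 17.5 and 12.9 RPKM in the second wild-type population.

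**Figure D1:**
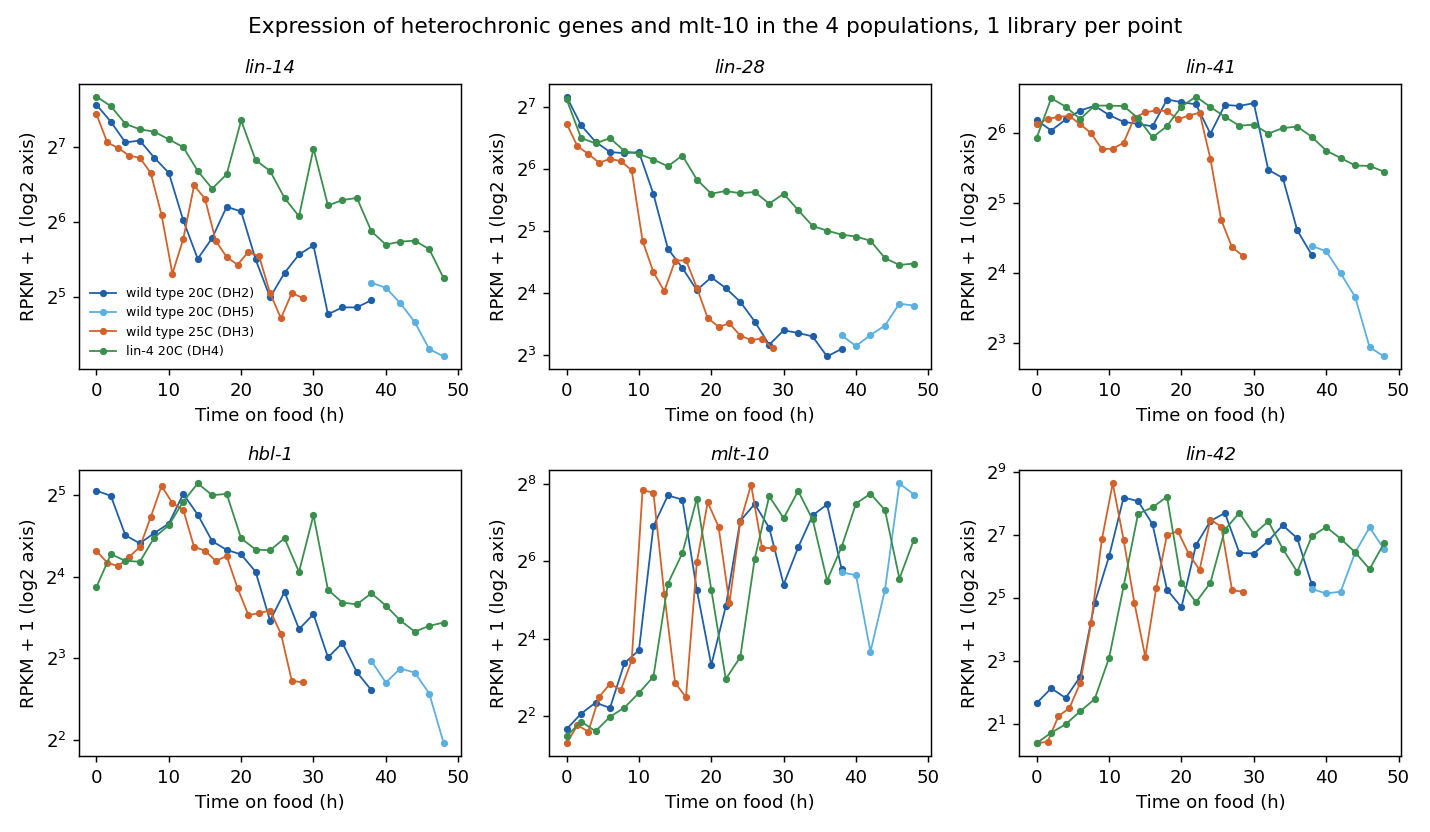
RPKM + 1 on a log2 axis against hours on food for lin-14, lin-28, lin-41, hbl-1, mlt-10 and lin-42, with 1 library per point and 1 line per population (DH2 and DH5 wild type at 20C, DH3 wild type at 25C, DH4 lin-4 at 20C). lin-14 and lin-28 stay higher in lin-4, at 57.9 and 29.8 RPKM at 38 h against 30.2 and 7.60 RPKM in wild type, while mlt-10 rises and falls in every population.

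Cyclic expression was first measured in wild type at 20C. Of 12767 genes tested over 17 libraries, 1745 (13.7%) oscillated at the fitted period of 11.25 h, with a median peak-to-trough range of 1.83 log2. With all time points 925 did at that same period, while the scan of periods ended at 12 h, the end of the range tried. The hedgehog-related gene grl-21 had a range of 4.95 ± 0.91, the collagen col-39 of 4.50 ± 0.75, the collagen dpy-8, which shapes the body, of 4.14 ± 0.80, and the hedgehog-related genes grl-7 and wrt-1 of 4.14 ± 0.97 and 4.14 ± 0.81. The small secreted peptide genes fipr-3, fipr-7, fipr-6 and fipr-9 ranged by 4.55 ± 0.61, 4.39 ± 0.65, 4.29 ± 0.67 and 4.14 ± 0.55, and nspb-6 by 4.36 ± 0.49. Members of such families are alike in sequence, and how reads matching several of them were divided is not given in the sources used here.

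The cuticle collagen list, which besides collagens holds dpy-18 (1.24 ± 0.24), a subunit of the prolyl hydroxylase that modifies them, oscillated in 103 genes, 86.6% of those tested (105 when adjusted over the list alone), including col-160 and col-12 with ranges of 4.00 ± 0.81 and 3.95 ± 0.67. Their share exceeded that of other genes by Fisher's exact test (adjusted p = 4.6e-71). That test takes genes as independent, while the list counts col-166 under 2 identifiers with ranges of 2.18 each, and other collagens, as col-126 and col-127, have near-equal values. Hedgehog-related genes oscillated in 33 of 38 (33 adjusted over the list alone), molting factors in 25 of 31 (25), astacin proteases in 20 of 25 (20), patched-related genes in 16 of 23 (17) and pharyngeal cuticle genes in 11 of 11 (11). Examples are the molting factors qua-1 (3.48 ± 0.74), mlt-9 (3.22 ± 0.78), mlt-11 (3.20 ± 0.73) and mlt-10 (3.10 ± 0.72), the collagen-processing protease nas-37 (3.36 ± 0.55) and abu-8 (4.04 ± 0.61). Epidermal antimicrobial peptides followed in 8 of 16 (8), as nlp-24 with 2.26 ± 0.36, and pharynx muscle and gland genes in 8 of 17 (9), as phat-2 with 2.77 ± 0.54. Epidermis and seam transcription factors oscillated in 5 of 15 (5), among them nhr-73 (2.29 ± 0.30), grh-1 (1.93 ± 0.33) and nhr-23 (1.60 ± 0.31), a nuclear receptor needed for molting. Heterochronic genes, which time larval fates, oscillated in 4 of 20 (4): lin-42 (2.61 ± 0.66), the worm relative of the clock gene period, mab-10 (2.03 ± 0.40), nhr-23 and lin-29. Starvation genes did so in 3 of 21 (3), intestine genes in 3 of 23 (3), as the protease gene cpr-4 (1.43 ± 0.13), and heat shock genes in 2 of 47 (2), hsp-43 and dnj-27.

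Housekeeping and germline lists did not cycle at this size. limma called 0 of 29 germline genes (5 at an unadjusted p under 0.05), 0 of 73 ribosomal protein genes (0), 0 of 26 neuron genes (7), 0 of 31 cell cycle genes (6), 0 of 20 body wall muscle genes (4), 0 of 20 vulva and gonad genes (5), 0 of 9 sperm genes (1), 0 of 5 male development genes (0) and 0 of 8 reference genes (2). Both lin-4 targets passed limma's adjusted p with ranges below the minimum of 1 log2. lin-14 ranged by 0.75 ± 0.16 (adjusted p = 0.0089) and lin-28 by 0.51 ± 0.11 (adjusted p = 0.011). lin-41, hbl-1 and daf-12 had ranges of 0.36 ± 0.13, 0.13 ± 0.14 and 0.22 ± 0.12 and did not pass.

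Mean peak times of the lists are given here without a test between lists. Counted within the 11.25 h cycle from 0 h, oscillating epidermis and seam transcription factors peaked at 0.591 h on average, heterochronic genes at 0.792 h and molting factors at 1.32 h. Means for hedgehog-related and patched-related genes were 3.55 h each, and those for astacin proteases 4.88 h, collagens 4.97 h, pharyngeal cuticle genes 5.56 h, pharynx genes 6.56 h and antimicrobial peptides 8.30 h. Peaks of pharynx genes, patched-related genes and collagens were scattered over the cycle (concentration 0.362, 0.376 and 0.398), so their means place few single genes. The collagen dpy-8 peaked at 0.949 h and the collagen col-39 at 6.92 h.

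**Figure D2:**
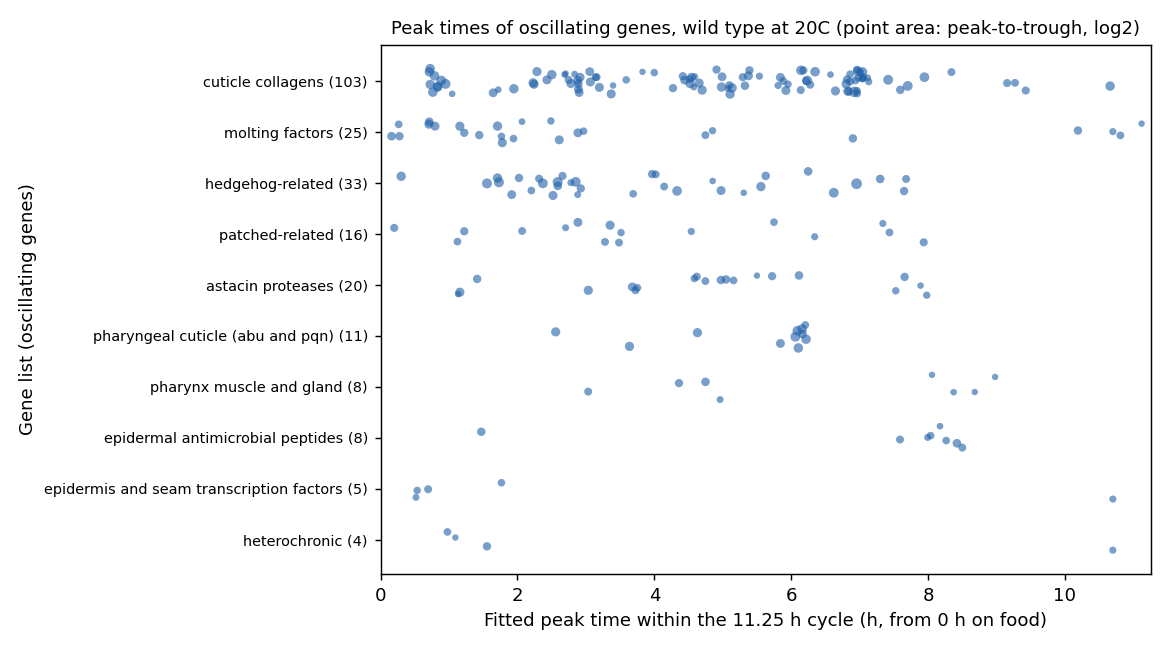
Fitted peak time in hours within the 11.25 h cycle (horizontal) of each oscillating gene in wild type at 20C, 1 point per gene, grouped by gene list with the number of genes, point area scaling with the peak-to-trough range in log2. Molting factors average 1.32 h and antimicrobial peptides 8.30 h.

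At 25C the fitted period was 7.75 h over 4.5 to 28.5 h. With all time points the scan ended at 12 h, the end of its range, in both wild-type series, and so placed no period within that range. A fit of all time points at 7.75 h called 10 genes at 25C. The molting factor mlt-10 had local maxima above 100 RPKM at 10.5, 19.5 and 25.5 h at 25C, and at 14, 26 and 36 h at 20C. At 7.75 h, 1412 of 12980 genes (10.9%) oscillated over 17 libraries, with a median range of 1.94 log2. The largest ranges were those of the collagens col-12 (5.44 ± 1.07), col-161 (5.24 ± 0.90) and col-162 (5.08 ± 0.84), the pharyngeal cuticle genes abu-8 (5.34 ± 0.75) and pqn-5 (5.05 ± 0.74), and the hedgehog-related genes grl-16 (5.31 ± 0.88), grd-6 (5.07 ± 0.75) and grl-21 (5.06 ± 1.22). Both temperatures called 1125 genes where independent lists would share 191. Across these 1125 genes, which are not independent replicates, peaks kept one order: the phase differences had a concentration of 0.978. Ranges correlated with r = 0.954 over all 12638 genes tested at both temperatures. Most of those genes were not called, so this r does not describe the shared genes alone.

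By list, limma called 75 of 120 collagens (98 adjusted over the list alone), 17 of 39 hedgehog-related genes (35), 17 of 31 molting factors (26), 17 of 26 astacin proteases (21), 11 of 22 patched-related genes (14), 10 of 11 pharyngeal cuticle genes (11), 9 of 17 pharynx genes (9), 7 of 15 antimicrobial peptides (9), 7 of 15 epidermis and seam transcription factors (8) and 5 of 20 heterochronic genes (7). Among them were fbn-1 (4.21 ± 0.79), sym-1 (4.53 ± 1.06), nhr-23 (2.54 ± 0.43), lin-46 (1.21 ± 0.21) and the intestinal proteases cpr-1 (1.62 ± 0.19) and cpr-5 (1.45 ± 0.12). lin-14 had a range of 0.78 ± 0.16 (limma adjusted p = 0.016), again below 1 log2, and so did lin-28 (0.62 ± 0.16, adjusted p = 0.041) and lin-41 (0.40 ± 0.09, adjusted p = 0.027). mlt-10 (3.26 ± 0.97, adjusted p = 0.061), lin-42 (2.82 ± 0.92), lin-29 (1.26 ± 0.41), hbl-1 (0.39 ± 0.12) and daf-12 (0.12 ± 0.20) did not pass. This count depended on the fit: 874 genes passed with a linear trend, 403 at a period 1 h longer, 2 at a period 1 h shorter, 10 with all time points and 809 without the 13.5 h library.

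The lin-4 mutant cycled with many of the same genes. The period was 12 h, the end of the range fixed in advance, where 1155 of 12857 genes (8.98%) oscillated with a median range of 2.01 log2. At a period 1 h shorter 0 did, with all time points 747, and without single time points 627 (without 18 h) to 1468 (without 6 h). With periods up to 16 h, chosen after the data were seen, the period was 14 h and 1742 genes passed. At 14 h, 81.2% of the genes called in wild type were called in lin-4 (1393 genes), against 58.3% at 12 h. Peaks kept the wild-type order, with a concentration of phase differences of 0.975 over 1000 genes at 12 h and of 0.970 at 14 h. At 12 h the largest ranges were those of grl-7 (4.62 ± 0.80), grl-5 (4.52 ± 0.71), col-149 (4.37 ± 0.85), grl-16 (4.33 ± 0.69), col-41 (4.18 ± 0.84), lgc-22 (4.14 ± 0.72), col-17 (4.08 ± 0.88), dpy-4 (4.07 ± 0.86), the lipase gene lips-6 (4.07 ± 0.84) and grl-15 (4.01 ± 0.72).

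In that mutant series, limma called at 12 h 83 of 112 collagens (102 adjusted over the list alone), 30 of 38 hedgehog-related genes (34), 19 of 31 molting factors (22), 14 of 25 astacin proteases (14), 12 of 22 patched-related genes (16), 8 of 10 pharyngeal cuticle genes (10), 5 of 17 pharynx genes (7), 4 of 17 antimicrobial peptides (6), 3 of 15 epidermis and seam transcription factors (4) and 3 of 20 heterochronic genes (3). These were lin-42 (2.35 ± 0.61), mab-10 (2.16 ± 0.42) and nhr-23 (2.04 ± 0.39), and mlt-10 ranged by 3.07 ± 0.69. lin-41 (0.33 ± 0.08) and lin-29 (0.98 ± 0.26) passed limma's adjusted p (0.029 and 0.045) with ranges under 1 log2, and hbl-1 (0.35 ± 0.17) and daf-12 (0.24 ± 0.08) did not pass. At 14 h the calls were 92.9% of collagens, 33 of 38 hedgehog-related genes, 25 of 31 molting factors, 10 of 17 antimicrobial peptides, 9 of 17 pharynx genes and 5 of 15 epidermis and seam transcription factors. Heat shock genes, with 0 of 47 calls at 12 h, had 10 at 14 h.

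**Figure D3:**
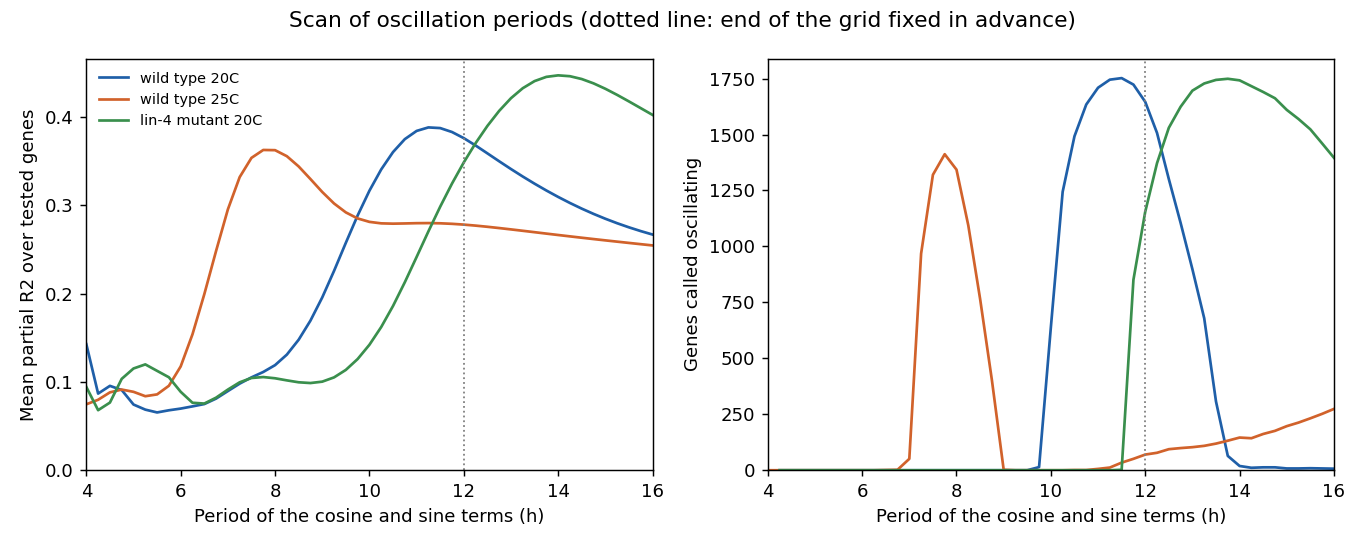
Mean partial R2 of the cosine and sine terms over tested genes (left) and number of genes called oscillating (right) against the period in hours, 1 line per series of 17 libraries. The partial R2 curves peak at 11.25 h in wild type at 20C, 7.75 h at 25C and 14 h in lin-4, beyond the dotted line at 12 h that ends the range fixed in advance.

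Whether lin-4 changes the size of an oscillation was asked first of lin-14. Its range was 0.50 ± 0.18 log2 in the mutant (limma adjusted p = 0.13), a difference from wild type of -0.24 ± 0.24 that did not pass (p = 0.31, normal approximation, 17 libraries in each series). At 14 h the range was 0.44 ± 0.20 and the difference -0.31 ± 0.26 (p = 0.23). lin-28 ranged by 0.17 ± 0.08, a difference of -0.35 ± 0.14 from wild type (p = 0.014, adjusted p = 0.13 over 9 named genes). lin-42, mlt-10 and nhr-23 differed by -0.25 ± 0.90, -0.03 ± 1.00 and 0.44 ± 0.50, and lin-41, hbl-1, lin-29 and daf-12 by -0.03 ± 0.15, 0.22 ± 0.22, -0.12 ± 0.39 and 0.02 ± 0.15, none past the test. At 14 h lin-42 and mlt-10 turned to 0.58 ± 0.74 and 0.49 ± 0.89, and hbl-1 went to 0.40 ± 0.21. No named gene passed the adjusted p there, so the signs for lin-42 and mlt-10 depend on the period. Of 1866 genes oscillating in either series, 6 passed an adjusted p under 0.05, the only limit in this test, while the same test called 13 unchanged genes (0.781%) in simulated data, so false calls among the 6 are not excluded. They are named here although the rule does not take them: fipr-11 (-2.67 ± 0.51), C53D6.7 (-1.75 ± 0.37), ckb-2 (-1.51 ± 0.31), dod-17 (-1.06 ± 0.25) and C06H2.7 (-0.70 ± 0.18) ranged less in lin-4 and C01G6.3 (1.15 ± 0.28) more. With a linear trend limma's ranges gave 0 such genes where the spline fit gave 6, at 14 h they gave 11, and leaving out single time points gave 3 (without 26 h) to 21 (without 20 h).

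Trends were fitted as a linear change beside the cycle, which need not be steady. Over 6 to 38 h in wild type at 20C, limma called 1206 rising and 2100 falling genes over 17 libraries, of which 694 and 2016 were not called oscillating. With median-of-ratios rescaling the split was 1524 and 1623, as the median of all genes moved from -0.09 to 0.10. The largest rises were in the collagens col-161 (8.49 ± 1.14 log2), col-162 (8.02 ± 0.88), col-12 (7.95 ± 1.32), col-133 (7.50 ± 0.63) and col-13 (7.47 ± 1.23). The largest falls were in the caveolin gene cav-1 (-6.20 ± 0.66), dod-3 (-6.01 ± 0.38), clec-42 (-4.61 ± 0.19), the linker histone C01B10.5, also called hil-7 (-4.18 ± 0.56) and tag-293 (-4.12 ± 0.37). Both lin-4 targets fell, lin-28 (-3.41 ± 0.32) and lin-14 (-1.77 ± 0.20), as did hbl-1 (-2.21 ± 0.22) and lin-41 (-1.26 ± 0.39), 2 further heterochronic regulators. lin-41 was at 79.2 RPKM at 6 h and still at 85.3 RPKM at 30 h, and dropped to 18.1 RPKM by 38 h. lin-29, the transcription factor of the adult switch, rose by 2.40 ± 0.32, and mab-10 rose by 2.40 ± 0.43. mlt-10 (1.87 ± 0.87), lin-42 (0.61 ± 0.83), nhr-23 (-0.57 ± 0.38) and daf-12 (-0.47 ± 0.38) did not pass.

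Of the collagens 76 rose, 2 fell and 41 did not pass (76 and 2 adjusted over the list alone), and of 29 germline genes 25 rose (25), as the helicase glh-1 (3.72 ± 0.18) and the P granule gene pgl-1 (3.17 ± 0.13). Pharyngeal cuticle genes rose in 9 of 11 (10), as pqn-5 (5.58 ± 1.01). Astacin proteases rose in 12 and fell in 3 of 25 (14 and 3), hedgehog-related genes rose in 11 and fell in 1 of 38 (9 and 1), body wall muscle genes rose in 6 of 20 (6), as unc-27 (1.77 ± 0.16), and molting factors rose in 4 and fell in 1 of 31 (2 and 0). Neuron genes fell in 17 of 26 (17), among them egl-3 (-2.30 ± 0.11), eat-4 (-2.28 ± 0.17) and ida-1 (-2.28 ± 0.14). Epidermis and seam transcription factors fell in 8 of 15 (9), as egl-18 (-1.68 ± 0.14). Starvation genes fell in 7 of 21 (7), vulva and gonad genes fell in 6 and rose in 1 of 20 (6 and 1), heat shock genes fell in 9 and rose in 2 of 47 (9 and 2), as hsp-16.2 (-3.27 ± 0.34), and cell cycle genes fell in 3 of 31 (3). Among genes with a mean RPKM of at least 5, 3 of 15 starvation genes fell, and the median of that list went from -0.37 to 0.13. Ribosomal protein genes rose in 1 of 73 (1), rpl-11.1 (2.79 ± 0.14), and reference genes in 1 of 8 (1), csq-1 (1.48 ± 0.19). Pharynx genes rose in 2 and fell in 5 of 17 (2 and 5), intestine genes rose in 2 and fell in 1 of 23 (2 and 1), antimicrobial peptides rose in 4 and fell in 4 of 16 (4 and 4), patched-related genes rose in 2 and fell in 2 of 23 (2 and 2), and male development genes rose in 3 and fell in 1 of 5 (3 and 1). No list passed camera with an estimated correlation: collagens, germline, neurons and male development were lowest (adjusted p = 0.38 with an estimated correlation). For sperm and heat shock genes camera pointed up while their medians were -0.08 and -0.07, which rescaling turned to 0.06 and 0.12.

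Trends at 25C shared many genes with those at 20C. limma called 1447 rising and 2164 falling genes, or 1696 and 1650 after rescaling, which moved the median of all genes from -0.14 to 0.07. Both temperatures shared 908 rising genes (133 expected by independent lists) and 1539 falling genes (336 expected), with 5 in opposite directions. lin-28 (-3.27 ± 0.30), lin-14 (-1.73 ± 0.18) hbl-1 (-2.01 ± 0.24) and lin-41 (-1.23 ± 0.43) fell, and lin-29 rose by 2.53 ± 0.43 and mlt-10 by 3.42 ± 1.08. lin-42 (2.24 ± 1.12), nhr-23 (-0.77 ± 0.63) and daf-12 (-0.07 ± 0.55) did not pass. The largest changes were col-161 (9.53 ± 1.45), col-73 (9.51 ± 2.04), col-12 (9.09 ± 1.54), col-17 (9.02 ± 2.15) and dpy-13 (8.97 ± 2.06), and cav-1 (-5.73 ± 0.80), clec-15 (-5.26 ± 0.54), clec-13 (-5.25 ± 0.53), clec-17 (-4.72 ± 0.50) and dct-19 (-4.43 ± 0.70). Germline genes rose in 25 of 28 (25 adjusted over the list alone; camera adjusted p = 0.048 with an estimated correlation), collagens in 84 of 120 (87), and neuron genes fell in 20 of 26 (20). For cell cycle, starvation, heat shock, intestine, sperm and ribosomal genes camera pointed up with medians below 0, and pharynx genes had a median of -0.77 with a mean of 0.20. Rescaling turned the medians of ribosomal (-0.02 to 0.22), intestine (-0.08 to 0.15), starvation (-0.10 to 0.11), heat shock (-0.11 to 0.11), reference (-0.12 to 0.11) and sperm genes (-0.13 to 0.00).

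In lin-4, limma called 1158 rising and 1988 falling genes, or 1562 and 1104 after rescaling, which moved the median of all genes from -0.25 to 0.08. lin-28 (-1.44 ± 0.10), hbl-1 (-1.05 ± 0.28) and nhr-23 (-1.25 ± 0.43) fell, while the changes of lin-14 (-0.96 ± 0.20) and lin-41 (-0.32 ± 0.11) stayed below 1 log2. With all time points nhr-23 went the other way (1.27) and did not pass (limma adjusted p = 0.10). mlt-10 (4.99 ± 0.89), lin-42 (3.69 ± 1.16) and lin-29 (1.29 ± 0.33) rose, and daf-12 (0.06 ± 0.12) did not pass. Rises were led by col-73 (10.38 ± 1.70), col-17 (10.33 ± 1.91), dpy-4 (10.04 ± 1.78), grl-16 (9.99 ± 1.29) and dpy-5 (9.93 ± 1.84), and falls by scl-5 (-4.12 ± 0.36), clec-42 (-3.47 ± 0.23), the proneural gene hlh-3 (-3.33 ± 0.76), gst-24 (-3.25 ± 0.76) and spp-18 (-2.81 ± 0.36). Collagens rose in 83 and fell in 5 of 112 (85 and 5 adjusted over the list alone; camera adjusted p = 0.039 with an estimated correlation), hedgehog-related genes rose in 29 and fell in 2 of 38 (29 and 2), germline genes rose in 19 of 28 (19) and neuron genes fell in 19 of 26 (19). For vulva and gonad, starvation, heat shock, intestine, sperm and pharynx genes camera pointed up with medians below 0. Among genes with a mean RPKM of at least 5 the starvation median went from -0.44 to 0.51. Rescaling turned the medians of heterochronic (-0.28 to 0.03), ribosomal (-0.17 to 0.19), heat shock (-0.12 to 0.24), intestine (-0.06 to 0.29), reference (-0.21 to 0.15) and sperm genes (-0.01 to 0.26).

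Which genes depend on lin-4 was asked first at equal labelled times. Over 17 pairs from 6 to 38 h, lin-28 was higher in lin-4 by 1.44 ± 0.18 log2 (limma adjusted p = 1.2e-05), and lin-14 by 0.97 ± 0.11 (adjusted p = 5.9e-06), just below the minimum of 1 log2. limma called 48 genes higher and 99 lower of 12855. Higher were the chemoreceptor genes srbc-15 (4.33 ± 0.10) and srw-85 (4.28 ± 0.14), the glucuronosyltransferase ugt-13 (3.09 ± 0.29), the lectin gene clec-209 (3.08 ± 0.15), whose values follow those of the neighbouring F56A4.2, and pqn-60 (2.18 ± 0.14). Lower were the collagens col-161 (-2.09 ± 0.51), col-77 (-2.07 ± 0.45) and col-162 (-1.95 ± 0.47), mab-7 (-2.07 ± 0.39) and the F-box gene fbxa-192 (-1.98 ± 0.05). The second wild-type population lay on the lin-4 side of the first at 38 h for srw-85 (12.1 RPKM against 0.343 RPKM, and 31.8 RPKM in lin-4), ugt-13 (6.36, 0.571 and 34.1 RPKM) and fbxa-192 (1.57, 9.44 and 1.67 RPKM).

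Collagens were lower in 18 of 115 genes (8 adjusted over the list alone; camera adjusted p = 0.044 with an estimated correlation), as col-156 (-1.85 ± 0.38), and pharyngeal cuticle genes in 4 of 11 (4), as abu-1 (-1.63 ± 0.39). Hedgehog-related genes were lower in 2 of 38 (1), grd-14 (-1.82 ± 0.51) and grd-6 (-1.44 ± 0.48), astacin proteases in 2 of 25 (1), nas-23 (-1.03 ± 0.38) and nas-36 (-1.02 ± 0.34), and molting factors in 1 of 31 (0), again nas-36. Medians of molting factors (-0.31) and hedgehog-related genes (-0.33) turned to 0.06 and 0.01 when lin-4 was shifted by 4 h. In the heterochronic list lin-28 was higher and lin-46 lower (-1.04 ± 0.22), with hbl-1 (0.50 ± 0.10), lin-41 (0.23 ± 0.14), lin-29 (-0.80 ± 0.20), lin-42 (-0.50 ± 0.40) and daf-12 (-0.26 ± 0.12) below 1 log2. Of these, lin-41 (limma adjusted p = 0.21), lin-42 and daf-12 did not pass the adjusted p either. mlt-10 (-0.59 ± 0.43) and nhr-23 (-0.17 ± 0.28) did not pass. The sex-determination gene her-1 was lower (-1.85 ± 0.09), the 1 call in 5 male development genes (1; camera adjusted p = 0.033 with an estimated correlation, or 0.47 at the fitted clock described below). hsp-16.41 was higher (1.09 ± 0.29), the 1 call in 47 heat shock genes (1), and fell short of 1 log2 after rescaling (0.99) and at that clock (0.85). limma called 0 of 73 ribosomal protein genes (34 at an unadjusted p under 0.05), 0 of 29 germline genes (4), 0 of 26 neuron genes (18), 0 of 31 cell cycle genes (13), 0 of 23 intestine genes (4) and 0 of 16 antimicrobial peptides (3). For heterochronic, germline, sperm, vulva and gonad, pharynx, intestine, antimicrobial, and epidermis and seam factor lists camera pointed down while medians were above 0, against a median of all genes of 0.09, and the means of sperm and intestine genes were -0.05 and -0.02. Rescaling turned the medians of the heterochronic, germline, sperm, intestine, and epidermis and seam factor lists below 0 (-0.05, -0.06, -0.01, -0.08 and -0.05).

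The mutant population ran behind wild type. Correlations of lin-4 with wild-type libraries over oscillating genes, which are not independent replicates, averaged 0.782 at equal times and 0.906 with lin-4 delayed by 4 h. A delay of 4 h was the longest tried, and r still rose there from 0.889 at 2 h, so a longer delay is not excluded. Single libraries differed: lin-4 at 20 h matched wild type at 18 h best, and lin-4 at 38 h matched wild type at 32 h. With wild-type values taken at a fitted clock, an alternative chosen after the data were seen, 95 genes were called (35 higher, 60 lower) and 88 of 146 earlier calls remained. lin-28 stayed higher (1.17 ± 0.16), lin-14 was 0.75 ± 0.09 higher, srbc-15 4.37 ± 0.08 and pqn-60 2.15 ± 0.13, while col-161 went to -1.23 ± 0.28 and mab-7 to -1.71 ± 0.21. Collagens were then lower in 10 of 117 (10 adjusted over the list alone; camera adjusted p = 0.29 with an estimated correlation), pharyngeal cuticle genes in 2 of 11 (2) and hedgehog-related genes in 1 of 38 (1). No call remained in astacin proteases (0 of 25), molting factors (0 of 31) or heat shock genes (0 of 47).

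**Figure D4:**
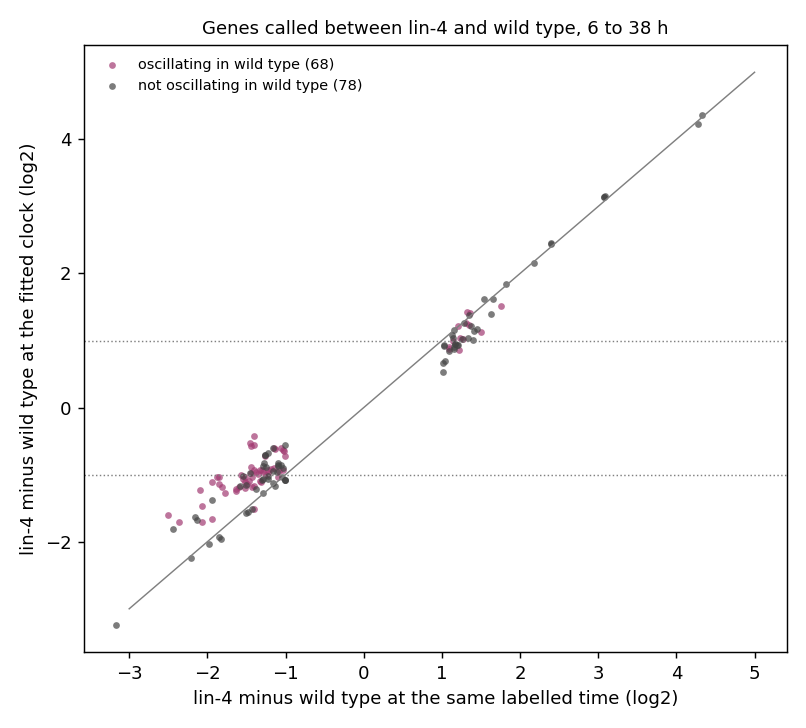
Change of lin-4 against wild type at the fitted clock (vertical, log2) against the change at the same labelled time (horizontal, log2), 1 point per gene called at the same time, coloured by whether it oscillates in wild type (68 genes) or not (78), with the diagonal and dotted lines at 1 and -1. Most lower genes move toward 0, as col-161 from -2.09 to -1.23, and srbc-15 stays near the diagonal at 4.33 and 4.37.

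**Figure D5:**
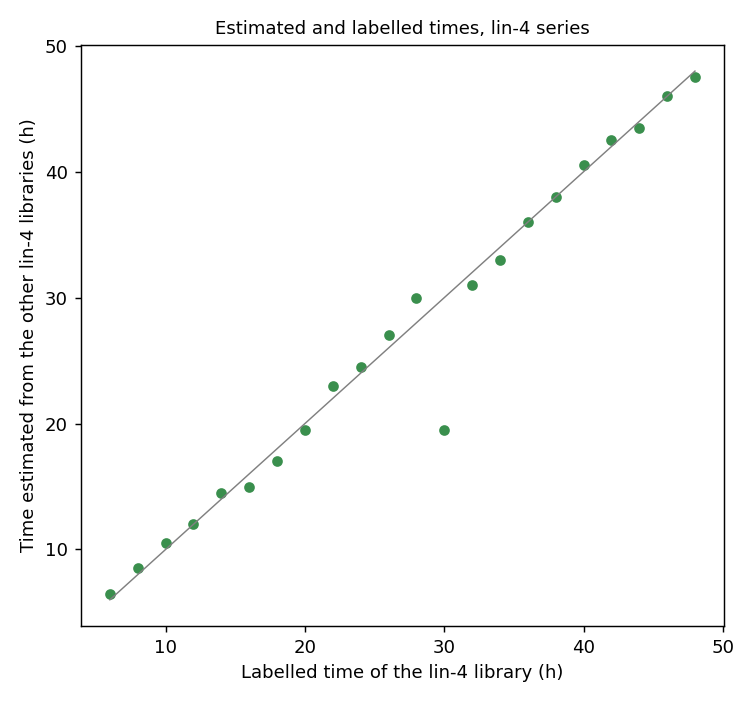
Time estimated from the other lin-4 libraries with 2011 trending genes (vertical, h) against labelled time (horizontal, h) for lin-4 libraries from 6 to 48 h, 1 point per library. The library labelled 30 h lies at 19.5 h, while the largest error of the 21 others is 2 h.

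Whether the gap between lin-4 and wild type changed with time was asked next. From 6 to 38 h the difference grew for lin-28 by 1.99 ± 0.34 log2 (limma adjusted p = 0.0027) and for hbl-1 by 1.16 ± 0.20 (adjusted p = 0.0025), and for lin-14 by 0.94 ± 0.29 (adjusted p = 0.047), just short of 1 log2. After rescaling lin-14 reached 1.04 and was called, as it was over 0 to 38 h (1.26, limma adjusted p = 0.0041). But lin-14 did not pass limma's adjusted p with lin-4 shifted by 4 h (0.80, adjusted p = 0.16) or without the lin-4 30 h library (0.92, adjusted p = 0.069). With the shift hbl-1 did not pass either (0.61, adjusted p = 0.065), and lin-28 did (2.00). For lin-41 the change of the difference was 1.13 ± 0.37, short of limma's adjusted p (0.062), but passed after rescaling (1.23, adjusted p = 0.024) and without the pair of 28 h (1.22, adjusted p = 0.043) or the lin-4 30 h library (1.27, adjusted p = 0.035), and was 0.43 at the fitted clock. For lin-29 it was -1.34 ± 0.58 (adjusted p = 0.14), which passed over 0 to 38 h (-1.78, adjusted p = 0.026), with the shift (-1.61, adjusted p = 0.011) and at that clock (-1.46, adjusted p = 3.3e-04). lin-42 (2.49 ± 1.19), mlt-10 (1.69 ± 1.38), daf-12 (0.68 ± 0.35) and nhr-23 (0.05 ± 0.95) did not pass. limma called 261 genes with a rising and 195 with a falling difference of 12855, or 348 and 167 after rescaling. Rising were the pharyngeal gland gene phat-5 (4.99 ± 1.41), fip-6 (3.53 ± 0.95), the antimicrobial peptide cnc-4 (3.38 ± 0.67), tag-297 (2.76 ± 0.80) and the chaperone hsp-16.2 (2.70 ± 0.66). Falling were col-133 (-4.94 ± 1.18), fipr-11 (-4.23 ± 1.03), fbxa-72 (-3.52 ± 0.91), the lipid-binding far-2 (-2.16 ± 0.37) and cyp-13A12 (-2.09 ± 0.39).

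Antimicrobial peptides rose against wild type in 4 of 16 genes (6 adjusted over the list alone), as nlp-33 (2.30 ± 0.52), heat shock genes rose in 4 and fell in 1 of 47 (8 and 1), as F44E5.5 and F44E5.4 (3.07 ± 0.68 and 2.98 ± 0.66, a near-identical pair), and starvation genes rose in 3 of 21 (4; camera adjusted p = 0.033 with an estimated correlation), as gei-7 (2.54 ± 0.60). Vulva and gonad genes rose in 3 and fell in 1 of 20 (3 and 1), as lin-1 (1.05 ± 0.16) and lin-11 (-1.45 ± 0.36), but at the fitted clock lin-1 (0.89), lin-11 (-0.66) and lin-31 (0.54) were under 1 log2. Heterochronic genes rose in 2 of 20 (4 up and 1 down), and collagens rose in 2 and fell in 5 of 115 (1 and 4). Germline genes fell in 2 of 29 (2), him-3 (-1.33 ± 0.26) and htp-1 (-1.26 ± 0.32), but at that clock the list median went from -0.54 to 0.24, him-3 to 0.00 and htp-1 to 0.12. Single calls in lists were the ribosomal protein gene rps-28 (-1.06 ± 0.21), rnt-1 (1.19 ± 0.18), her-1 (1.06 ± 0.16), fat-7 (-1.39 ± 0.41), nas-27 (-1.84 ± 0.50) and abu-9 (-3.07 ± 0.68). At that clock 893 genes were called (636 up, 257 down), with lin-28 at 2.11, lin-14 at 0.82 and hbl-1 at 0.68. For male development genes camera pointed up with a median of -0.75, and for pharynx genes up with a mean of 0.42 and a median of -0.01, or 0.09 after rescaling.

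From 38 to 48 h, lin-4 was set against the second wild-type population over 6 pairs. lin-28 was higher by 1.22 ± 0.18 log2 (limma adjusted p = 0.0096) and lin-41 by 1.96 ± 0.20 (adjusted p = 0.0044), and lin-14 by 0.92 ± 0.11 (adjusted p = 0.0058), again below 1 log2. hbl-1 (0.86 ± 0.13), daf-12 (0.73 ± 0.10) and lin-29 (-0.96 ± 0.24) also passed limma's adjusted p (0.0097, 0.0074 and 0.034) under 1 log2, and mlt-10 (0.84 ± 0.86), lin-42 (0.72 ± 0.48) and nhr-23 (0.24 ± 0.45) did not pass. srbc-15 (4.75 ± 0.10), lips-6 (3.99 ± 0.67), pqn-60 (3.09 ± 0.28), cnc-4 (3.08 ± 0.50) and the nuclear receptor nhr-74 (2.75 ± 0.38) were higher. The collagens col-38 (-5.99 ± 1.38), col-112 (-5.69 ± 1.27), col-138 (-5.21 ± 1.47), bli-2 (-5.17 ± 1.39) and col-71 (-4.85 ± 1.21) were lower. limma called 156 genes higher and 346 lower of 13077. With lin-4 delayed by 4 h (4 pairs), the only delay tried here, the split turned to 315 higher and 112 lower. What a longer delay would leave was not tested. col-138 (-2.65, adjusted p = 0.084) and bli-2 (-3.37, adjusted p = 0.080) then did not pass limma, and col-38 (-3.77), col-112 (-3.52) and col-71 (-2.68) did with smaller changes. Without the pairing by time 191 of 295 called genes were higher, and without 44 h 179 genes were called.

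Sperm genes were lower in 41 of 56 (41 adjusted over the list alone), as the major sperm protein genes msp-53 (-2.49 ± 0.50) and msp-56 (-2.46 ± 0.45), with a list median of -1.80 (camera adjusted p = 0.42 with an estimated correlation). With the 4 h delay 3 of 45 sperm genes were lower, the median was -0.71, and msp-53 (-0.96) fell short of 1 log2. Yolk protein genes were lower in 2 of 6 (3), vit-6 (-3.57 ± 0.91) and vit-1 (-2.18 ± 0.30), collagens lower in 10 and higher in 1 of 137 (0 and 0), and antimicrobial peptides higher in 6 of 15 (6), as nlp-29 (1.92 ± 0.40). Epidermis and seam transcription factors were higher in 3 of 15 (3), nhr-74, nhr-73 (1.65 ± 0.32) and ceh-16 (1.03 ± 0.09, or 0.77 with the delay, under 1 log2), heterochronic genes in 2 of 20 (2) and astacin proteases in 2 of 25 (2), as nas-3 (2.54 ± 0.27). fat-7 (-1.61 ± 0.21) and the male regulator mab-3 (-1.75 ± 0.16) were lower. Of the 139 genes called at 6 to 38 h and tested here, 85.6% had the same sign and 58 were called in the same direction. For hedgehog-related, astacin, vulva and gonad, pharynx, intestine and male development lists camera pointed down with medians above 0, against a median of all genes of 0.12 that rescaling moved to -0.01. Rescaling also turned the medians of pharynx (-0.04) and intestine genes (-0.11).

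Temperature was compared after scaling. 25C libraries matched 20C libraries best at a time factor of 1.3 (mean r = 0.922 across genes, which are not independent replicates). The fitted periods of 11.25 h at 20C and 7.75 h at 25C differ by a larger factor. The temperature fit used cosine and sine terms at 11.25 h of aligned time for both series. Calls of oscillating genes could therefore hold a misfit of the cycle, which was not tested. limma called 152 genes higher and 66 lower at 25C of 12868, or 128 and 90 after rescaling. Higher were srw-85 (3.24 ± 0.16 log2), the lectins clec-15 (2.98 ± 0.17) and clec-13 (2.97 ± 0.17), ugt-13 (2.62 ± 0.29) and the small heat shock gene hsp-16.41 (2.41 ± 0.25). Lower were the fatty acid desaturase fat-7 (-3.01 ± 0.15), ins-13 (-1.77 ± 0.25), acdh-1 (-1.41 ± 0.26), dpy-8 (-1.34 ± 0.44) and dpy-3 (-1.32 ± 0.40). srw-85, ugt-13 and hsp-16.41 also lay 3.28, 2.23 and 1.52 log2 above the first 20C population in the second one at 38 h.

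Heat shock genes were higher in 6 of 47 (6 adjusted over the list alone), as hsp-16.2 (1.70 ± 0.21), hsp-16.48 and hsp-16.49 (1.19 ± 0.14 each, a pair with equal values). Collagens were lower in 11, higher in 1 and not called in 107 (11 and 1 over the list alone), as sqt-3 (-1.29 ± 0.42) and dpy-17 (-1.25 ± 0.19). Starvation genes were higher in 3 and lower in 1 of 20 (3 and 1), F46B6.8 (2.04 ± 0.16), hacd-1 (1.07 ± 0.20), F54F3.3 (1.04 ± 0.18) and acs-2 (-1.13 ± 0.30). The Piwi gene prg-1 (1.82 ± 0.05) was the 1 germline gene called of 29 (1), and mlt-11 (-1.01 ± 0.39), wrt-2 (-1.21 ± 0.35), nhr-74 (-1.04 ± 0.20), cnc-2 (-1.02 ± 0.12) and her-1 (-1.15 ± 0.07) were single lower genes of their lists. lin-14 (0.08 ± 0.08), lin-28 (0.07 ± 0.06) hbl-1 (0.10 ± 0.06), lin-29 (-0.05 ± 0.16), mlt-10 (-0.49 ± 0.30) and nhr-23 (-0.27 ± 0.24) did not pass limma's adjusted p. lin-41 (-0.23 ± 0.06), lin-42 (-0.80 ± 0.22) and daf-12 (-0.29 ± 0.07) passed it with changes under 1 log2. limma called 0 of 20 heterochronic genes (7 at an unadjusted p under 0.05). No list passed camera with an estimated correlation (lowest adjusted p = 0.44 with an estimated correlation), and for neuron, pharynx, sperm, body wall muscle and intestine genes camera pointed down with medians above 0, which rescaling turned below 0 in each (-0.07, -0.03, -0.03, -0.04 and -0.10).

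The lin-4 and the 25C comparison share the first 20C wild-type population. Their changes correlated with r = 0.293 across 12725 genes, against a mean of 0.484 in 100 simulated pairs of unchanged populations, and their covariance was 0.0291 against 0.00494 simulated. They shared 10 higher and 9 lower genes, where independent lists give 0.460 and 0.513, and 4 genes were called in opposite directions. Some of the 19 shared genes have near-equal changes, as F56A4.2 with clec-209, and nspc-2 with nspc-5 and nspc-6. They are therefore not independent, which the numbers for independent lists do not allow for. With the wild-type libraries split between the comparisons, each way shared 17 genes, all among these 19, where independent lists give 0.590 and 0.466.

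Feeding was compared with arrest over 3 populations. The antimicrobial saposin-like genes spp-17 (6.93 ± 0.18 log2) and spp-23 (6.22 ± 0.16), ugt-22 (5.25 ± 0.17), the lysozyme ilys-5 (5.16 ± 0.56) and the metallothionein mtl-2 (4.79 ± 0.19) were higher in fed larvae. The acyl-CoA synthetase acs-2 (-6.74 ± 0.90), the alcohol dehydrogenase sodh-1 (-5.88 ± 0.62), fmo-2 (-5.58 ± 0.61), the glyoxylate cycle gene gei-7 (-5.49 ± 0.95) and the linker histone hil-1 (-4.94 ± 0.17) were lower. limma called 1184 genes higher and 1357 lower of 13370. After rescaling 1536 were higher and 1023 lower, as the median of all genes moved from -0.15 to 0.00.

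Cell cycle and replication genes were higher in 19 of 31 (19 adjusted over the list alone), as rnr-1 (2.37 ± 0.28), cdk-1 (2.31 ± 0.38) and mcm-4 (2.21 ± 0.27), and intestine genes higher in 8 and lower in 2 of 23 (9 and 2), as cpr-5 (4.21 ± 0.56) and fat-5 (-2.49 ± 0.71). Starvation genes were lower in 11 and higher in 1 of 25 (12 and 1). Heat shock and folding genes were higher in 9 and lower in 2 of 48 (9 and 2), as hsp-60 (2.47 ± 0.20) and hsp-12.6 (-2.58 ± 0.28), molting factors higher in 6 of 27 (6), as nhr-23 (1.55 ± 0.18), and neuron genes lower in 4 of 26 (4), as flp-1 (-1.15 ± 0.15). Collagens were higher in 13 and lower in 19 of 87 (13 and 19), as col-149 (4.76 ± 0.43) and col-153 (-2.76 ± 0.29). Antimicrobial peptides were lower in 6 and higher in 2 of 18 (6 and 2), patched-related genes lower in 4 and higher in 2 of 20 (4 and 2), epidermis and seam transcription factors higher in 4 of 15 (3) and ribosomal protein genes higher in 1 and lower in 1 of 73 (1 and 1). Of the reference genes, eif-3.C (2.18 ± 0.19) and tba-1 (1.15 ± 0.17) were higher, 2 of 8 (2). lin-14 and lin-28 changed by -0.49 ± 0.14 and -0.72 ± 0.15, lin-42 by 0.98 ± 0.15 and mlt-10 by 0.75 ± 0.19, under 1 log2. lin-41 (0.17 ± 0.14), hbl-1 (-0.14 ± 0.22), lin-29 (-0.03 ± 0.22) and daf-12 (0.09 ± 0.15) did not pass. No list passed camera with an estimated correlation (lowest adjusted p = 0.75 with an estimated correlation). For collagens camera pointed up with a median of -0.21, which was 0.22 among genes of at least 5 RPKM, and for body wall muscle and heterochronic genes it pointed up with medians of -0.14, or 0.03 after rescaling.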

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

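Tests of later development over all called genes and by the size of the change left, of the DH2 population alone, of a wrong label, an exchange and low depth, of noise in shared libraries, and of DH2 against the other 20C wild-type population were chosen only after the results were seen, as was the fitted clock. The difference between lin-4 and wild type changed from 6 to 38 h by a test of that change itself for lin-28 (1.99 log2), hbl-1 (1.16) and lin-14 (0.94, under 1 log2). With lin-4 shifted by 4 h neither hbl-1 nor lin-14 passed the adjusted p. lin-14 also missed it without the lin-4 30 h library, and hbl-1 was under 1 log2 at the fitted clock. For lin-41 (1.13) the change missed limma's adjusted p (0.062), which it passed after rescaling (1.23) and without the lin-4 30 h library (1.27). At the fitted clock the change for lin-41 was under 1 log2. For lin-29 (-1.34, limma adjusted p = 0.14) the change passed over 0 to 38 h (-1.78), with lin-4 shifted by 4 h (-1.61) and at the fitted clock (-1.46). Outside the genes used, entries without a gene name took up to 3.03% of summed RPKM in a library, a signal that was not analysed here. For lin-14, lin-28 and the other quantities tried in the 6 DH5 libraries, 11 in all, no library stood apart from the rest by Dixon's ratio.

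The genes called between lin-4 and wild type at equal times were weighed first. Against wild type at the fitted clock, 88 of 146 (60.3%) kept call and direction, and the median change went from 1.34 (interquartile range 0.41) to 1.06 (0.33), while calls near the minimum of 1 log2 ended. Over this whole set the values argue against a delay of this linear form as the whole cause. Among oscillating genes 55.9% kept their call with a median going from 1.401 (0.33) to 1.03 (0.27), and among the others 64.1% with one going from 1.29 (0.47) to 1.08 (0.64), all with the same sign. For the others a delay of this linear form is argued against as the whole cause and stays open as a part. For the oscillating genes a delay stays open as the whole cause. Their share lay only just above the limit set beforehand, and the clock aligned the populations imperfectly (r = 0.823 over genes oscillating in either series). Scaling is argued against by the 148 genes called after rescaling. Against the other wild-type population, 85.6% of the 139 genes tested had the same sign, and 58 were called in the same direction. Both comparisons use the same lin-4 population, whose delay could keep the sign, so this share does not decide on a fault of DH2. Such a fault stays open. For srw-85, ugt-13 and fbxa-192 the other wild-type population lay on the lin-4 side of DH2 at 38 h. An effect of lin-4 stays open as a hypothesis, untested against a difference between populations, which the design does not separate from genotype.

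The library labelled lin-4 30 h was weighed next. Its time, estimated from 2011 trending genes, was 19.5 h, -10.5 h from its label and 13.4 SD of the errors of 21 others. No other lin-4 library (0) was more than 6 h off, which argues against an exchange within the series, and its depth of 25.1 M reads had rank 7 of 25 from the lowest, which argues against low depth. A wrong label may be the cause, and so may a mixture, since the best mixture of other libraries gave 42.7% to 18 h, 35.3% to 20 h and 21.9% to 34 h. No biological explanation was tested.

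The 19 genes that differ from DH2 in the same direction in lin-4 and at 25C were weighed last. Noise of the shared libraries is argued against by the 17 of them called in both comparisons when these had no wild-type library in common, whichever way the libraries were divided, and scaling by the 19 genes shared after rescaling. A difference between DH2 and the other 20C wild-type population stays open. Only 15 of the 19 genes were tested in lin-4 against that population, where their median change was 1.16 (interquartile range 0.70), 69.8% of the 1.66 at 6 to 38 h, and 25C was not set against it. The second population lay above or below DH2 at 38 h by a median of 44.3% of the lin-4 change with a wide spread (0.73, interquartile range 1.57), so a difference of DH2 itself cannot be told apart from shared effects of genotype and warmth for these genes. Such a difference may hold for srw-85, ugt-13, fbxa-156, hsp-16.41, ugt-10, C14A11.5 and fbxa-192, which differed by 1 log2 or more between the 2 populations, and were named after their values were seen.

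Other splits of the samples bear on chance. For lin-4 against wild type 2 of 100 splits, the real one included, called at least 147 genes, and for its change with time 1 of 100 called at least 456 (highest other 377). At 38 to 48 h it was 1 of 32 for 502 genes (highest other 28), and for 25C against 20C 1 of 100 for 218 genes (highest other 0). For these 4 the share is under 0.05 among such exchanges of time points. Neighbouring time points of a population are not independent, so this does not exclude chance. Other splits of the first (highest 282 genes) and of the second point to a structure of the samples. These splits exchange time points of single populations, which are no replicates of a genotype or temperature, and leave differences between populations open. For fed against arrested larvae, 1 of 10 splits reached 2541 genes (highest other 0), and 10 splits are too few for a share under 0.05.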

How the results depend on the processing

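Chosen after the data were seen were the fitted clock, periods up to 16 h, the fits without the lin-4 30 h library and the 4 h lag at 38 to 48 h. Of the values of named genes under all alternatives, 14015 kept direction and side of the threshold, 1058 fell short of it, 56 newly passed, 82 moved and 5 reversed. These 5 were, with all time points, cpr-1 (0.030) in the wild-type 20C trend and nhr-23 (1.27), cdk-1 (0.20) and cpr-1 (0.076) in the lin-4 trend, and htp-1 (0.12) in the change with time at the fitted clock. The cause was not tested.

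With all time points, 925, 10 and 747 genes oscillated in wild type at 20C, at 25C and in lin-4, each at the period of its main fit. Scans of all time points gave periods of 12 h in both wild-type series, and 5046 genes had a trend in lin-4. At 25C, 2 genes oscillated with a period 1 h shorter, 403 with one 1 h longer and 874 with a linear trend. In lin-4, limma called 0 with a period 1 h shorter (1155 at its own period), 1742 with periods up to 16 h and 1812 without the 30 h library, both at 14 h. With a mean RPKM of at least 5, where fewer genes are tested, trends numbered 2068, 2240 and 1938, changes with time 296, and genes called at 38 to 48 h 214. With a pseudocount of 0.1, which enlarges changes of low genes by construction, lin-4 against wild type gave 252, 38 to 48 h 894 and 25C against 20C 398. The 4 h lag gave 96 genes for lin-4 against wild type, and the clock 95, and 893 for its change with time. Amplitude differences numbered 0 with a linear trend and 11 with periods up to 16 h. Except for the pseudocount and the filter, the cause was not tested.

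Without the block of paired time points or populations, 38 to 48 h gave 295 genes, lin-4 against wild type 105 (45 higher, 60 lower) and fed against arrested larvae 2325, and with pairs 25C against 20C gave 216. A fit of the lin-4 phase with the wild-type period in both series gave no value.

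Leave-one-out ranges were 1483 to 1822, 809 (without 13.5 h) to 1872 and 627 to 1468 for oscillation in wild type at 20C, at 25C and in lin-4, and 2956 to 3357, 3121 to 3762 and 2670 to 3321 for trends. In lin-4 the moves were 697 without 16 h, 627 without 18 h, 663 without 24 h and 634 without 26 h. Ranges were 123 to 162 for lin-4 against wild type, 322 to 509 for its change with time, 205 to 237 for 25C against 20C and 2162 to 2914 for fed larvae. At 38 to 48 h they ran from 179 (without 44 h) to 462, with 222 without 42 h, 255 without 46 h and 238 without 48 h. Amplitude differences ran from 3 (without 26 h) to 21 (without 20 h), with 11 without 8 h, and that of lin-14 from -0.32 to -0.16.

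Depth was 12.3 to 36.5 M reads, so changes of genes near 1 RPKM rest on few reads, and the filter and the pseudocount moved the counts above.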

Other observations

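Gene families formed from shared name prefixes were compared with the other tested genes by Fisher's exact test. Benjamini-Hochberg adjustment was over 1192 tests, all chosen only after the data were seen. Genes on one of the gene lists above were left out of their families, so the counts are of the remaining members. Of the neuropeptide families, flp genes fell with time in 23 of 27 (adjusted p = 2.2e-12) and nlp genes in 20 of 24 (1.4e-10) in wild type at 20C, and in 25 of 27 (4.7e-15) and 20 of 24 (1.6e-10) at 25C. Globin genes (glb) fell in 23 of 33 (1.1e-09) and receptor guanylate cyclases (gcy) in 14 of 17 (2.3e-07) at 20C. Histone genes (his) rose in 41 of 64 (6.9e-21) at 25C and in 18 of 58 (5.2e-05) in lin-4, but in 1 of 64 in wild type at 20C, where the family did not pass (0.22). Calls within a family are not independent, and each series is 1 population, so these counts show no effect of temperature or genotype. Whether poly(A) selection or reads shared between histone genes shaped them was not tested. The nspb genes, small and alike in sequence, oscillated in 12 of 12 (2.7e-09) and the transthyretin-like ttr genes in 21 of 43 (1.4e-06) at 20C.

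In fed against arrested larvae, proteasome genes (rpn) were higher in 8 of 11 (adjusted p = 1.5e-05), glucuronosyltransferases (ugt) in 21 of 61 (1.2e-06) and C-type lectins (clec) in 29 of 102 (4.6e-07). Glutathione transferases (gst) were lower in 15 of 42 (2.0e-04) and F-box genes (fbxa) in 29 of 113 (5.2e-05). At 25C, fbxa genes were higher in 10 of 89 (3.7e-06) and clec genes in 10 of 99 (8.2e-06).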
